A study of Mus musculus with 8 samples.

How the data were processed

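The samples were 8 libraries of total RNA from lavage cells of C57BL/6J wild-type mice, 4 after whole-body cigarette smoke and 4 after room air, over 8 weeks. The smoke came from reference cigarettes at an average of 150 mg of particulate matter per m3, for at least 2 hours a day on 5 days a week, in mice 6 to 12 weeks old that were matched for sex and age. Lavage cells went straight into an RNA preservative and lysis reagent (Trizol), and RNA was prepared with a Qiagen micro kit and libraries with a Bioo kit. The labels give no batch, sex, pairing or hour of lavage, and whether macrophages were sorted is not given in the sources used here. Groups came from the treatment label, and replicates were numbered in the order of the deposited samples.

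The deposited table holds a signal per gene and library: read counts that the authors divided by 1 DESeq size factor per library, which is stated in the header of the deposited size factors. Multiplying each value by its library's size factor gave a whole number within 0.1 for 100% of values, so whole reads were recovered. The submitters' notes name the genome build mm10 and the tools Bowtie2, STAR, SAMtools and DESeq2; the role and version of each, the read counter, the annotation release, the strandedness and any filter are not given in the sources used here. The deposited size factors carry no unit, and are a kind of value other than signal. Gene positions, names and types came from GENCODE M21 on GRCm38, which matched 36649 of the 36689 gene identifiers; of entries sharing a symbol, the one with most reads kept it.

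Depth ran from 6942153 to 13241859 recovered reads per library and genes with reads from 27490 to 34851. A count of 0 allows up to 3 reads, which is 2.46 to 4.97 normalized counts. PCR reads carry no molecular identifiers, so such limits cover counting error only. Each pair of libraries of a group differed by more than counting noise (smallest chi-square per degree of freedom 6.40), so none was a copy of another. Xist and Ddx3y were read in each library as a check of the mice.

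Genes with a mean of at least 10 normalized counts were tested (15950 of 36689). The test was limma 3.58.1 in R 4.3.3 (lmFit, eBayes with an intensity trend) on log2(normalized count + 1), smoke minus room air, two-sided, with Benjamini-Hochberg adjusted p under 0.05 over all tested genes as the threshold for a call. Means and SD are of normalized counts over 4 libraries per group, and log2 fold changes and SE are from limma. For each gene list the calls over all genes were counted, then the calls with p adjusted over the list alone. Lists with at least 5 measured members were tested with camera at its preset correlation of 0.01 between genes, adjusted over 39 lists; camera with a correlation estimated per list and fry were alternatives. Marker scores were means of log2(normalized count + 1) over a list's measured members, compared by an exact two-sided permutation test of 70 assignments, adjusted over 17 lists. Pearson and Spearman correlations across libraries used 20000 permutations.

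The test, the filter, the 43 gene lists (26 of pathways and functions, 17 of cell types and RNA quality), the alternatives and the rule for named genes were set before the data were examined, except where a sentence says otherwise. The rule took, among called genes with a mean of at least 50, a log2 change of at least 1 in size, no overlap between groups and a given name, the 12 largest rises and 12 largest falls; up to 4 members per list with the smallest adjusted p, or up to 2 of the highest mean in a list with no call; and 19 genes of smoke response, inflammation, metals and reference whatever they showed. With 4 clock genes chosen after the data were seen, the named genes held 107 called ones. In 105 of them the groups did not overlap, and 56 were called in each of the 8 fits without 1 library.

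Alternatives were pseudocounts of 0.5 and 5, no filter, a mean of at least 50, TMM factors, quantile normalization, edgeR 4.0.16 (quasi-likelihood), DESeq2 1.42.0 and limma voom on the recovered reads, array weights, no genes of the X and Y chromosomes, and each library left out in turn. After the data were seen, a term for sex, a term for a clock gene score and the omission of the 3 libraries with the highest erythroid marker score were added. The tools were tested on simulated data made from these counts: limma called 62.7%, 91% and 97% of genes changed 1.5-, 2- and 4-fold, and 6.7% of its calls were unchanged genes, against 6.1% for edgeR, 17% for DESeq2 and 5.2% for voom. Camera called the 1 changed list and 0 of 40 unchanged ones. The simulated genes varied independently of each other, so this does not test camera on lists whose genes move together.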

Results

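RNA sequencing measured transcripts of the cells washed out of the lung airspaces of C57BL/6J wild-type mice that had breathed cigarette smoke or room air for 8 weeks. Each group held 4 libraries of total RNA from lavage cells, and whether these were sorted is not given. In a healthy lung lavage cells are mostly alveolar macrophages, beside other leukocytes, shed epithelium and red cells. The room air libraries held 11785732, 12253510, 13241859 and 10006469 reads (replicates 1 to 4). The smoke libraries held 6942153, 12921602, 11604098 and 12583074 reads. A count of 0 thus allows up to 3 reads, or 2.46 to 4.97 normalized counts depending on the library, for counting error only. Xist, expressed from the inactive X chromosome, was at 19990 to 24140 normalized counts in room air replicates 2 and 4 and smoke replicates 1 and 4. Ddx3y, a gene of the Y chromosome, was at 1198 to 1394 in the other 4 libraries, which gives 2 female and 2 male libraries in each group. Nothing in the labels says that each library comes from a separate mouse, so the p-values measure the spread between these samples. Spearman correlations across genes between pairs of libraries ran from 0.973 to 0.992; genes are not independent replicates.

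The comparison of smoke with room air addresses how 8 weeks of inhaled cigarette smoke change the transcriptome of lavage cells. Of 17 genes of antigen presentation on MHC class II and co-stimulation, 8 were lower after smoke, with H2-Aa at 791 ± 251 normalized counts against 3093 ± 75.7 in room air and H2-Eb1 at 387 ± 125 against 1727 ± 95.7. Such pairs of values are mean ± SD, n = 4 libraries per group. Of 15 immediate early genes 8 were lower too, and the inflammatory cytokine Il1b was at 77.6 ± 27.2 against 403 ± 204. Marco, a scavenger receptor that binds inhaled particles, was at 6552 ± 898 after smoke against 2456 ± 565. Gpnmb, a membrane glycoprotein of lipid-laden macrophages, was at 10950 ± 1729 against 4427 ± 1057. Of 38 genes of the lysosome 15 were higher, by smaller amounts, and 1 was lower. The 15 became 4 or 3 without room air replicates 2 or 4, and 7 or 5 without smoke replicates 1 or 4. Among those higher was Lamp1, a structural protein of the lysosomal membrane, at 12120 ± 593 against 9060 ± 275.

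Of 15950 genes tested with limma, 471 rose and 327 fell at an adjusted p under 0.05, and 3126 had an unadjusted p under 0.05. The genes that fell did so by more, with a median log2 change of -0.87 against 0.47 for those that rose, and 133 fell at least 2-fold against 69 that rose as much. In 784 of the 798 called genes the 4 smoke libraries lay entirely above or below the 4 room air libraries; this held for 12.8% of all tested genes, against 2.86% by chance. edgeR called 802 genes on the recovered reads. Leaving out 1 library moved the counts by over 1.5 times for room air replicate 2 (210 higher, 150 lower), room air replicate 4 (214 and 148), smoke replicate 1 (271 and 196) or smoke replicate 4 (235 and 181). So did leaving out the 3 libraries with the highest erythroid marker score, room air replicates 2 and 3 and smoke replicate 3 (210 and 159), an alternative added after the data were seen. Egr1, Cacnb3, Csf1r, Adgre1, Cxcr2 and Tax1bp1, whose calls held without any 1 library, lost them without these 3. That fit has fewer libraries in each group, which by itself can end calls. DESeq2 called 728 and 517, and quantile normalization gave 587 higher and 551 lower genes. A term for a score of 10 circadian clock genes, also added after the data were seen, left 0 called with limma, with 1483 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.163.

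**Figure D1:**
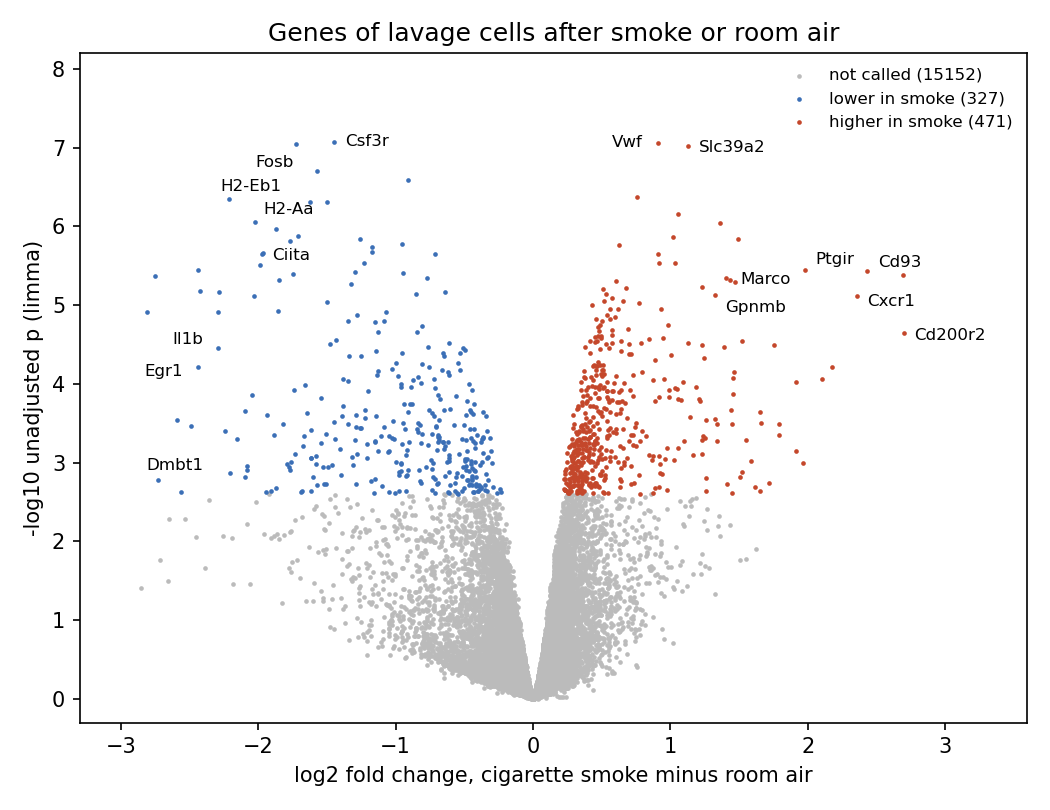
Each point is a gene of lavage cells, placed by its log2 fold change (cigarette smoke minus room air, n = 4 libraries per group) and the negative log10 of its unadjusted limma p. The 471 genes called higher are red and the 327 called lower are blue, and called falls reach -2.81 and called rises 2.7 on the log2 scale.

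Among the 12 largest rises, Cd200r2, of the CD200 receptor family, went from 21.9 ± 11.5 to 144 ± 57.8 normalized counts (log2 fold change 2.70, SE 0.370, adjusted p = 0.0041). Cd93, a transmembrane glycoprotein of myeloid and endothelial cells, lies on chromosome 2 from 148436640 to 148443563 of GRCm38 and rose from 313 ± 129 to 1616 ± 334 (log2 2.43, adjusted p = 0.00172). Cxcr1, a receptor for neutrophil-attracting chemokines on chromosome 1 from 74191785 to 74194631, rose from 201 ± 79.4 to 1010 ± 328 (log2 2.36). Ptgir, the prostacyclin receptor, rose by 1.98 on the log2 scale and Plpp3, a phosphatase of lipid phosphates, by 1.91. Ear6, a ribonuclease of the eosinophil-associated family, rose by 1.75, Dock3, an activator of Rac, by 1.65 and Stra6l, a retinol transporter, by 1.52. The other 4 were Map6 (1.79), Tsku (1.79), Ch25h (1.55) and Rragd (1.52). These 4 lost their call in at least 1 of the 8 fits without 1 library, with adjusted p up to 0.0543, 0.0532, 0.0549 and 0.0989. Map6 lost it without room air replicate 2 or smoke replicate 4, Tsku without room air replicate 2, Ch25h without smoke replicate 1, and Rragd without room air replicates 1, 2 or 4 or smoke replicate 1. Reads of the Ear family can be shared between its near-identical members.

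Among the 12 largest falls, Egr1, an immediate early transcription factor on chromosome 18 from 34859823 to 34864984, fell from 501 ± 213 to 89.9 ± 31.9 normalized counts (log2 -2.44, SE 0.375, adjusted p = 0.00673). Il1b, on chromosome 2 from 129364570 to 129371139, fell by 2.29 on the log2 scale (SE 0.330, adjusted p = 0.00482). Atp2b4, a calcium pump of the plasma membrane, fell from 356 ± 175 to 60.8 ± 10.5 and S100a6, a calcium-binding protein, from 205 ± 78.5 to 40.3 ± 12.8. Trp53i11 was at log2 -2.28, and Cacnb3, a calcium channel subunit that is also a marker of dendritic cells, at -2.05. Mir5107 (-2.03) lies within Cd74 on the same strand, so its reads are not separable from those of its host. Dmbt1 (-2.73) kept its call in 2 of the 8 fits without 1 library and Fscn1 (-2.21) in 3, with adjusted p up to 0.112 and 0.0999. Dmbt1 was called without smoke replicates 1 or 3, and Fscn1 without room air replicate 1 or smoke replicates 1 or 3.

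**Figure D2:**
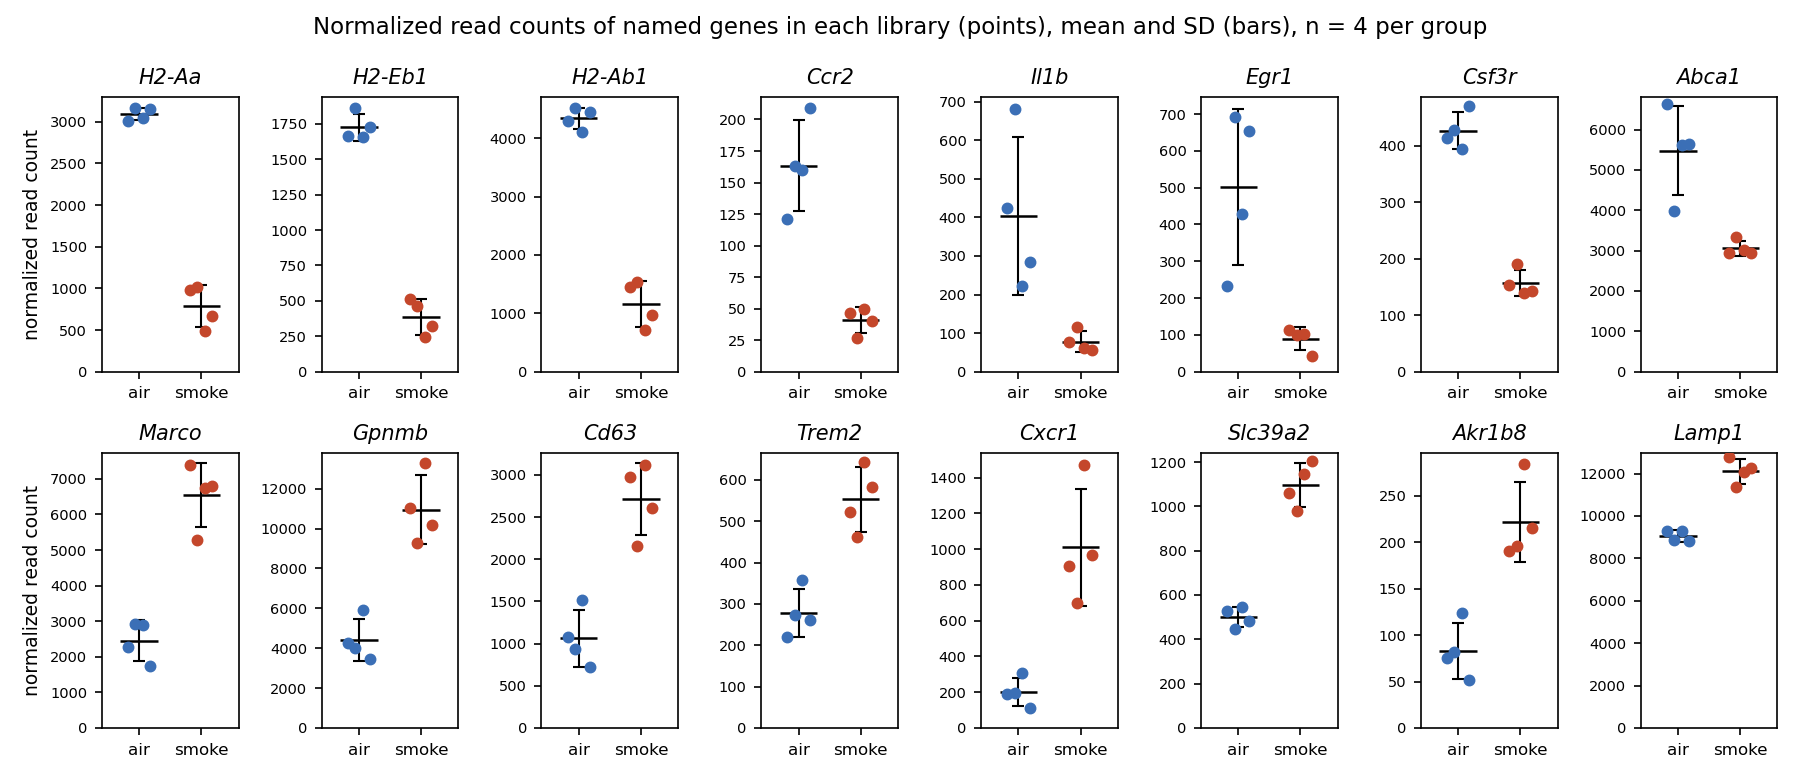
Normalized read counts of 16 genes in the 4 room air (blue) and 4 cigarette smoke (red) libraries, with the group mean and SD as bars and every axis starting at 0. In each panel the groups do not overlap: the smoke libraries hold 494 to 1012 counts of H2-Aa against 3010 to 3164 in room air, and 5277 to 7387 of Marco against 1735 to 2909.

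Of 17 measured genes of MHC class II presentation and co-stimulation, 8 fell, 0 rose and 9 did not pass, and 12 fell adjusted over the list alone. The list moved down with camera at an adjusted p of 2.75e-11, and adjusted p = 0.101 with an estimated correlation. Without any 1 library 8 fell too. H2-Eb1 (ENSMUSG00000060586, chromosome 17 from 34305867 to 34316674) fell by 2.21 on the log2 scale (SE 0.198, adjusted p = 0.00079). H2-Aa (chromosome 17 from 34282744 to 34287823) fell by 2.03 (SE 0.194), and H2-Ab1 (chromosome 17 from 34257689 to 34269419) fell from 4342 ± 184 to 1163 ± 394 normalized counts. H2-DMb1, a subunit of the exchanger that loads peptide, fell from 1025 ± 79.7 to 530 ± 67.1, and shares sequence with H2-DMb2. Ciita, the transactivator that class II genes require, fell from 601 ± 41.8 to 159 ± 51.8 and Cd74, the invariant chain of class II, from 13550 ± 651 to 3948 ± 1385, both chosen after their values were seen. With the clock score as a term the median log2 change of the 8 genes was -1.97 (median SE 0.36), against -1.91 (0.2) without it, and 0 of them passed with limma. Of class I, also chosen after the values were seen, H2-K1 (log2 -0.19), H2-D1 (0.073) and B2m (0.15) were not called. The dendritic cell marker score differed by -1.04 and the monocyte score by -0.74 on the log2 scale. In both, all 4 smoke libraries lay below all 4 of room air (exact permutation p = 0.0286 each).

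Of 15 immediate early genes, which switch on within minutes of stimulation or tissue handling, 8 fell, 0 rose and 7 did not pass, and 11 fell adjusted over the list alone. The immediate early list moved down with camera (adjusted p = 4.77e-10, and adjusted p = 0.101 with an estimated correlation). Without 1 library 7 to 10 fell. Fosb fell from 469 ± 90 to 156 ± 15.3 normalized counts (log2 -1.57, adjusted p = 0.00063), Fos from 2651 ± 541 to 1318 ± 197 and Btg2, an antiproliferative early gene, from 2583 ± 448 to 1070 ± 117. Of 15 inflammatory cytokines and mediators, 2 fell and 13 did not pass, with 5 lower and 1 higher adjusted over the list alone. The cytokine list moved down with camera (adjusted p = 0.0019, and adjusted p = 0.284 with an estimated correlation). Of cytokines, 1 fell without room air replicates 2, 3 or 4 or smoke replicates 1 or 4, and 4 without smoke replicate 2. Beside Il1b the other was Il12b, at 6.69 ± 2.94 against 30.4 ± 15.8, whose groups overlapped. Its call was kept in 2 of the 8 fits without 1 library (adjusted p up to 0.144), those without room air replicate 1 or smoke replicate 3. Tnf was at 402 ± 171 against 380 ± 174 (log2 0.11, adjusted p = 0.906) and was not called. Of 15 chemokines, 1 rose, 2 fell and 12 did not pass, with 1 and 5 adjusted over the list alone. The chemokine list moved down with camera (adjusted p = 0.0106, and adjusted p = 0.468 with an estimated correlation), and not without the 3 libraries with the highest erythroid score (adjusted p = 0.106). The 2 falls became 0 with limma without room air replicate 2 or smoke replicate 4, and 1 without room air replicate 3 or smoke replicates 1 or 2. Ccl6, an abundant macrophage chemokine, rose from 12780 ± 384 to 19130 ± 2401, while Cxcl1 was at 20.5 ± 10.7 against 18.7 ± 10 and was not called. Ccl2 lay below the filter, with 34 reads over the smoke libraries and 36 over those of room air, as did the noncoding RNA Ptgs2os2, with 10 and 12.

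Of 38 lysosomal hydrolase and membrane genes, 15 rose, 1 fell (Ctsf, chosen after its values were seen) and 22 did not pass, and 27 rose and 1 fell adjusted over the list alone. The list moved up with camera (adjusted p = 3.98e-11, and adjusted p = 0.183 with an estimated correlation). The 15 rises became 4 or 3 without room air replicates 2 or 4, and 7 or 5 without smoke replicates 1 or 4, and Ctsf lost its call without room air replicate 2 or smoke replicate 1. Beside Lamp1 (log2 0.42, SE 0.067, adjusted p = 0.00772), Atp6v0d2 rose from 12650 ± 664 to 18400 ± 1713 and Atp6v0c from 2335 ± 139 to 3187 ± 125, both subunits of the proton pump that acidifies lysosomes. Mcoln1, a lysosomal calcium channel, rose from 1105 ± 39.5 to 1349 ± 24, and lost its call without room air replicate 4 (adjusted p = 0.0534). Of 19 genes of lipid-associated macrophages, 8 rose, 1 fell and 10 did not pass, with 13 and 1 adjusted over the list alone. Psap and Lipa, among the rises, are also counted in the lysosomal list, and Ctsb and Ctsl among the matrix proteases. Spp1 (log2 0.23), Cd9 (0.18) and Lpl (-0.11) were among those not called. The lipid-associated list moved up with camera (adjusted p = 3.57e-06, and adjusted p = 0.256 with an estimated correlation). The 8 rises became 3 without room air replicates 2 or 4 or smoke replicate 1, 4 without smoke replicate 4, and 5 without room air replicate 1 or smoke replicate 3. Gpnmb (chromosome 6 from 49036546 to 49070929) rose by 1.32 on the log2 scale (adjusted p = 0.00213), Cd63, a tetraspanin of late endosomes, from 1061 ± 338 to 2714 ± 429, and Trem2, a receptor for lipids and cell debris, from 278 ± 58.3 to 553 ± 78.2.

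The fall within that list was Apoe, which is also a target of the sterol receptor LXR. Of 14 LXR targets of cholesterol efflux, 6 fell, 1 rose and 7 did not pass, with 8 lower and 2 higher adjusted over the list alone. The LXR list moved down with camera (adjusted p = 6.06e-05, and adjusted p = 0.315 with an estimated correlation). The 6 falls became 3 without room air replicate 4 and 2 without smoke replicates 1 or 4. The 1 rise became 2 without smoke replicate 3, and was lost without room air replicates 1, 2 or 4 or smoke replicates 1 or 4. Abca1, the exporter of cholesterol to apolipoproteins, fell from 5470 ± 1101 to 3053 ± 189 normalized counts (log2 -0.82, SE 0.133, adjusted p = 0.00847) and Arl4c, a small GTPase, from 473 ± 152 to 192 ± 24.2. Apoe was at 597 ± 111 against 1155 ± 373, and its call was lost without room air replicate 4 or smoke replicates 1, 3 or 4 (adjusted p up to 0.0801). Of 24 genes of cholesterol synthesis and uptake 0 were called with limma, edgeR, DESeq2 or voom (2 at an unadjusted p under 0.05) and 0 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.193). Without the 3 libraries with the highest erythroid score it passed in the opposite direction, up (adjusted p = 0.00865). Srebf2, the transcription factor of this pathway, was at 1572 ± 201 against 1557 ± 189.

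**Figure D3:**
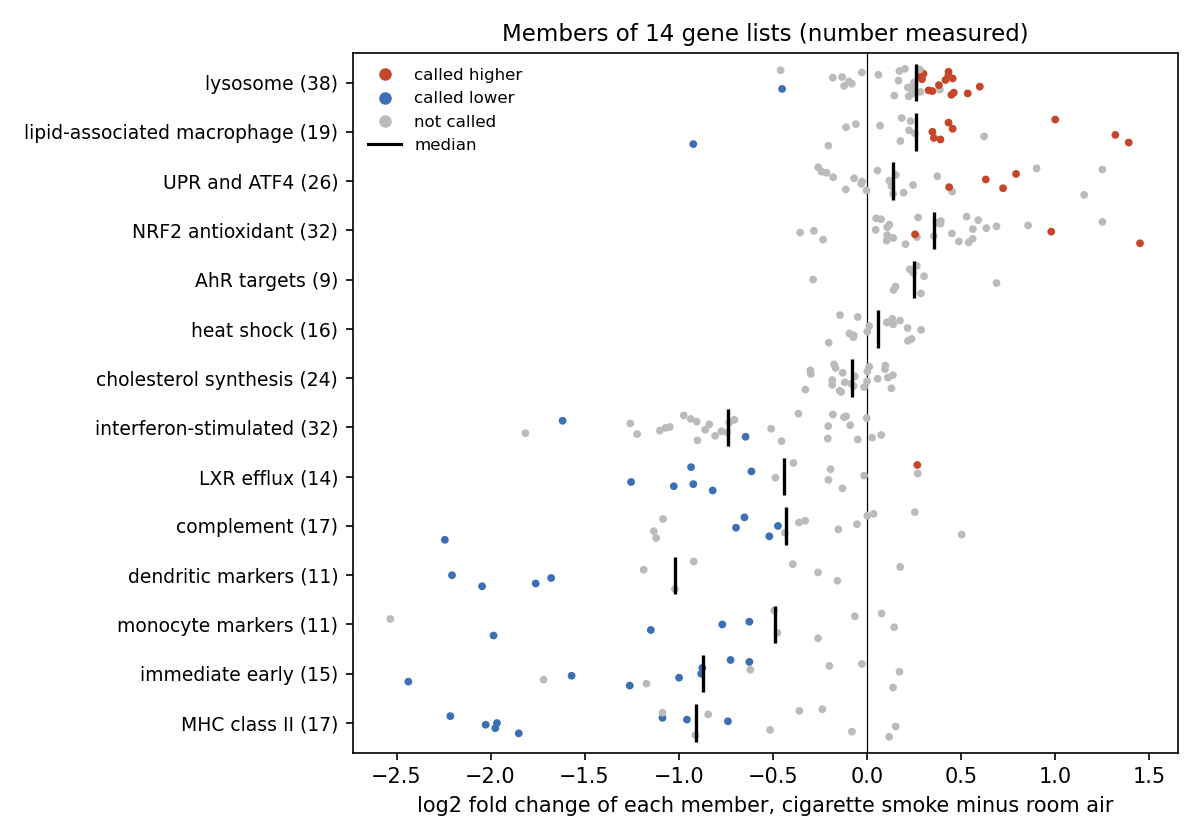
Log2 fold change (cigarette smoke minus room air) of each measured member of 14 gene lists, red where called higher, blue where called lower and grey where not called, with a black bar at the list's median and the number measured in brackets. The list labelled MHC class II also holds co-stimulation genes, and its median is -0.91. The median is -0.87 for immediate early genes, -0.74 for interferon-stimulated genes and 0.26 for lysosomal genes.

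Of 23 alveolar macrophage markers, 5 rose, 2 fell and 16 did not pass, with 10 and 5 adjusted over the list alone (camera adjusted p = 0.227). Without room air replicate 4, 1 of them fell. Marco (chromosome 1 from 120474538 to 120505024) rose by 1.44 on the log2 scale (adjusted p = 0.00178) and Slc39a2, a zinc importer, from 500 ± 43.8 to 1097 ± 99.1 normalized counts (adjusted p = 0.000383). Ctsk, a collagen-degrading cathepsin, rose from 3449 ± 443 to 5869 ± 430 and Car4, a carbonic anhydrase, from 2597 ± 109 to 4219 ± 548. Fabp1, a fatty acid-binding protein, fell from 719 ± 77.6 to 333 ± 95.6. Of 19 genes listed for the identity of these cells, mostly receptors and transcription factors, 3 rose, 1 fell and 15 did not pass, with 4 and 2 adjusted over the list alone (camera adjusted p = 0.909). In 6 of the 8 fits without 1 library none of these fell with limma, those without room air replicates 2, 3 or 4 or smoke replicates 1, 3 or 4, and 2 fell without room air replicate 1. Bhlhe41, a transcriptional repressor among them, rose from 2798 ± 489 to 4600 ± 450. The other rises were Tgfbr2 and Car4, the enzyme already counted among the markers. Tgfbr2 was called in 1 of the 8 fits without 1 library, that without smoke replicate 3 (adjusted p up to 0.138). Of 25 scavenger and efferocytosis genes, 3 rose, 3 fell and 19 did not pass, with 6 and 3 adjusted over the list alone (camera adjusted p = 0.926, median 0.06, mean -0.05). Of scavenger genes, 6 rose without smoke replicate 3, and 1 fell without room air replicates 2 or 4 or smoke replicates 1 or 4. Cd68 was among those that rose (log2 0.54), and Cd14, a lipopolysaccharide co-receptor, fell from 515 ± 102 to 258 ± 38.4. Of 18 matrix proteases and inhibitors, 4 rose, 4 fell and 10 did not pass, with 5 and 4 adjusted over the list alone (camera adjusted p = 0.993). The 4 rises became 1 without room air replicates 2 or 4 or smoke replicate 1, and 2 without room air replicate 1 or smoke replicate 3. The 4 falls became 0 with limma without room air replicate 2, 1 without smoke replicate 2, and 2 without room air replicate 4 or smoke replicates 1, 3 or 4. The macrophage elastase Mmp12 was at 69.1 ± 18.2 against 94.1 ± 25 (log2 -0.44, adjusted p = 0.309) and was not called. Of 12 alternative activation genes 1 fell, Irf4, and 11 did not pass, with 2 lower adjusted over the list alone (camera adjusted p = 0.312). The median was 0.03, the mean -0.12, and the median turned to -0.03 with quantile normalization. Irf4, at 62.7 ± 5.4 against 139 ± 46.2, lost its call without room air replicate 2 (adjusted p = 0.0584), and 2 of the list fell without smoke replicate 2.

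Of 32 NRF2 antioxidant and glutathione genes, 3 rose and 29 did not pass, with 5 higher adjusted over the list alone. The NRF2 list moved up with camera (adjusted p = 5.41e-07, and adjusted p = 0.485 with an estimated correlation). Akr1b8, an aldo-keto reductase, rose from 83.1 ± 29.9 to 222 ± 43.3 normalized counts (log2 1.45, adjusted p = 0.00792) and Gstm1, a glutathione transferase, from 2445 ± 411 to 4823 ± 736. Gsr, glutathione reductase, at 4187 ± 162 against 3505 ± 192, lost its call in each of the 8 fits without 1 library (adjusted p up to 0.137). Nqo1 was at 103 ± 36.7 against 63.7 ± 26.3 and Hmox1 at 4890 ± 1725 against 3314 ± 1093, and neither was called (adjusted p = 0.225 and 0.305). Of 9 targets of the aryl hydrocarbon receptor, which senses smoke hydrocarbons, 0 were called with limma, edgeR or voom and 2 with DESeq2, with 6 at an unadjusted p under 0.05. Adjusted over the list alone, 5 were higher. The receptor's list moved up with camera (adjusted p = 0.00622, and adjusted p = 0.259 with an estimated correlation). Without room air replicate 1, 1 of these targets rose. Ugt1a7c, whose exons are shared with other Ugt1a genes, was at 1216 ± 39.9 against 1014 ± 87.2. Ugt1a6a and Ugt1a6b are also among the 9, so the list's counts and its camera result count this locus repeatedly. Among the measured targets, Tiparp (log2 0.305, limma adjusted p = 0.0815) and Aldh3a1 (0.288, adjusted p = 0.873) were not called with limma, nor was Nqo1, also of this list. The targets Cyp1a1, Ahrr and Cyp1b1 lay below the filter. Cyp1a1 had 7 reads in each group, Ahrr 37 in smoke and 36 in room air, and Cyp1b1 47 in smoke, 36 of them in replicate 3, against 11. Of 9 metallothioneins and zinc transporters 1 rose, Slc39a2, and 8 did not pass, with the same count adjusted over the list alone. The list did not pass (camera adjusted p = 0.0857), but passed without the 3 libraries with the highest erythroid score (adjusted p = 0.0461), and 1 of its genes fell without smoke replicate 2. Mt1 was at 3351 ± 958 against 2738 ± 361 and Mt2 at 1028 ± 548 against 694 ± 159, and neither was called. Of 21 iron and haem genes 1 rose and 20 did not pass, with 2 higher and 1 lower adjusted over the list alone. The iron list did not pass (camera adjusted p = 0.0574), but passed without the same 3 libraries (adjusted p = 0.0219). The gene that rose was the transferrin receptor Tfrc, at 909 ± 123 against 432 ± 210, called in 1 of the 8 fits without 1 library, that without room air replicate 3 (adjusted p up to 0.08). In that fit 1 other iron gene fell, and without smoke replicate 4 1 other rose. The iron exporter Slc40a1 was at 287 ± 80.8 against 224 ± 54.5, not called.

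Of 26 genes of the unfolded protein response and ATF4, 4 rose and 22 did not pass, with 6 higher adjusted over the list alone. The ATF4 list moved up with camera (adjusted p = 0.00953, and adjusted p = 0.351 with an estimated correlation). The 4 rises became 1 without room air replicate 4 or smoke replicate 4, and 2 without room air replicates 2 or 3. Ddit3, a transcription factor of this response, rose from 185 ± 12.9 to 309 ± 59.4 normalized counts (log2 0.73, adjusted p = 0.0102). Psat1, of serine synthesis, was at 172 ± 26.9 against 99 ± 18.2 and lost its call without room air replicates 2 or 4 or smoke replicate 4 (adjusted p up to 0.0585). Of 21 p53 targets and senescence genes, 3 rose, 1 fell and 17 did not pass, with 7 and 1 adjusted over the list alone. The p53 list moved up with camera (adjusted p = 0.0218, and adjusted p = 0.183 with an estimated correlation). The 3 rises became 1 without room air replicates 2, 3 or 4 or smoke replicate 1. Gdf15, a stress cytokine, rose from 179 ± 42 to 419 ± 113, while Btg2, which fell, also belongs to the immediate early genes. Of 28 autophagy and mitophagy genes 3 rose and 25 did not pass, with 5 higher adjusted over the list alone. The autophagy list moved up with camera (adjusted p = 0.0157, and adjusted p = 0.49 with an estimated correlation). The 3 rises became 1 without room air replicates 2 or 4. Tax1bp1, a cargo receptor, rose from 3972 ± 172 to 4948 ± 71.6. Of 16 heat shock genes 0 were called with limma, edgeR, DESeq2 or voom (1 at an unadjusted p under 0.05) and 0 adjusted over the list alone (camera adjusted p = 0.827), with Hspa8 at 16050 ± 4202 against 14560 ± 3519. Of 42 cell cycle genes 2 rose and 40 did not pass, and 2 rose adjusted over the list alone. The cell cycle list moved up with camera (adjusted p = 3.97e-06, and adjusted p = 0.506 with an estimated correlation). The 2 called genes were Ccne2 (197 ± 46.4 against 119 ± 18.1) and Pcna (1125 ± 111 against 876 ± 81.5), called in 2 and 1 of the 8 fits without 1 library (adjusted p up to 0.118 and 0.116). Ccne2 was called without room air replicate 1 or smoke replicate 2 and Pcna without smoke replicate 2, where 3 of the list rose.

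Of 34 nuclear genes of oxidative phosphorylation 1 rose, Uqcrb (called in 2 of the 8 fits without 1 library, those without room air replicate 3 or smoke replicate 3), and 33 did not pass, with 0 adjusted over the list alone. The oxidative phosphorylation list moved up with camera (adjusted p = 0.0466, and adjusted p = 0.833 with an estimated correlation). The list's call was lost without the 3 libraries with the highest erythroid score (adjusted p = 0.33). Of 19 glycolysis genes 2 rose, 1 fell and 16 did not pass, with 4 and 3 adjusted over the list alone (camera adjusted p = 0.918). Of glycolysis calls, 1 of the 2 rises held without room air replicate 3 and neither without any other 1 library, and the fall held only without smoke replicates 2 or 3 (adjusted p of the 3 genes up to 0.117, 0.122 and 0.121). Of 25 fatty acid and PPAR genes 2 rose, 1 fell and 22 did not pass, with 4 and 4 adjusted over the list alone (camera adjusted p = 0.419). The 2 rises became 0 with limma without room air replicates 2 or 4 or smoke replicate 4, and the 1 fall became 2 without room air replicate 1. Cd36, a fatty acid and oxidized lipid receptor, was at 5165 ± 703 normalized counts against 3146 ± 646 and lost its call without room air replicates 2 or 4 or smoke replicate 4 (adjusted p up to 0.0584). Of 85 cytosolic ribosomal protein genes 0 were called with limma, edgeR, DESeq2 or voom (4 at an unadjusted p under 0.05) and 0 adjusted over the list alone. The list, with a median of 0.06, passed with camera (adjusted p = 0.0124 up, and adjusted p = 0.925 with an estimated correlation). Without the 3 libraries with the highest erythroid score its direction was the opposite, short of the threshold (adjusted p = 0.623). Of 35 mitochondrially encoded genes 0 were called with limma or those other tools (3 at an unadjusted p under 0.05) and 0 adjusted over the list alone (camera adjusted p = 0.26). Of 66 replication histones 1 fell, Hist1h4i (48.9 ± 4.4 against 80.5 ± 9.62), with the same count adjusted over the list alone (camera adjusted p = 0.825). It lost its call without room air replicate 2 or smoke replicate 4 (adjusted p up to 0.0536), and 2 histones fell without room air replicate 1. Of 28 named long noncoding RNAs 0 were called with limma or those other tools (1 at an unadjusted p under 0.05) and 0 adjusted over the list alone (camera adjusted p = 0.909, median 0.02, mean -0.01). Malat1 was at 135400 ± 15100 against 124500 ± 9583 and Neat1 at 12150 ± 631 against 12520 ± 776. The reference genes Actb (log2 -0.003) and Gapdh (0.11) were not called.

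Of 11 monocyte markers 4 fell and 7 did not pass, with 8 lower adjusted over the list alone. The monocyte list moved down with camera (adjusted p = 4.1e-06, and adjusted p = 0.101 with an estimated correlation). The 4 falls became 2 without room air replicates 2 or 4 or smoke replicate 1. Ccr2, the receptor that draws monocytes into tissue, fell from 163 ± 36.1 to 40.9 ± 10.3 normalized counts (log2 -1.98, adjusted p = 0.00157) and Itga4, an integrin of leukocyte adhesion, from 3737 ± 303 to 2208 ± 336. The other falls were Fn1 and Nr4a1, which is also counted among the immediate early genes. Fn1 was called in 3 and Nr4a1 in 2 of the 8 fits without 1 library (adjusted p up to 0.1125 and 0.0899). Of 11 dendritic cell markers 4 fell and 7 did not pass, with 7 lower adjusted over the list alone. The dendritic list moved down with camera (adjusted p = 4.81e-05, and adjusted p = 0.183 with an estimated correlation). The 4 falls became 1 without room air replicates 2 or 3 or smoke replicate 4, and 2 without smoke replicates 1 or 2, and 1 marker rose without smoke replicate 3. Cacnb3 fell from 94.2 ± 46.8 to 20.7 ± 5.99. Of 13 markers of interstitial and monocyte-derived macrophages 5 fell, 1 rose (Trem2) and 7 did not pass, with 6 and 1 adjusted over the list alone. The interstitial list moved down with camera (adjusted p = 0.0106, and adjusted p = 0.284 with an estimated correlation). The 5 falls became 1 without room air replicate 4, 2 without room air replicate 2 or smoke replicates 1 or 4, and 3 without room air replicate 1 or smoke replicate 3. Csf1r, the receptor for macrophage colony-stimulating factor, fell from 2894 ± 145 to 2087 ± 230. Of 17 complement genes 5 fell and 12 did not pass, with 10 lower and 1 higher adjusted over the list alone. The complement list moved down with camera (adjusted p = 8.35e-05, and adjusted p = 0.183 with an estimated correlation). The 5 falls became 0 with limma without room air replicates 2 or 4, and 2 without smoke replicate 1. C5ar1, a receptor for the anaphylatoxin C5a, was at 965 ± 201 against 1541 ± 140 and properdin, Cfp, at 369 ± 62.9 against 577 ± 73.8. C5ar1 lost its call without room air replicates 2 or 4 or smoke replicate 1 and Cfp without room air replicates 2 or 4 or smoke replicate 4 (adjusted p up to 0.0626 and 0.0729).

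Of 12 neutrophil markers 3 rose, 2 fell and 7 did not pass, with 5 and 4 adjusted over the list alone (camera adjusted p = 0.993 in the direction up, against a median of -0.11 and a mean of -0.07). The 2 falls became 1 without room air replicates 2 or 4 or smoke replicates 1 or 4. Receptors that neutrophils share moved apart. Cxcr1 and Cxcr2 rose, Cxcr2 from 67.9 ± 5.41 to 139 ± 35.8 normalized counts. Csf3r, the receptor for granulocyte colony-stimulating factor, fell from 427 ± 32.4 to 157 ± 23.7 (log2 -1.45, adjusted p = 0.000383). The neutrophil score differed by -0.07 between groups (exact permutation p = 0.571). S100a9, Retnlg, Ly6g, Mmp9 and Lcn2 of the neutrophil list were not among the measured, so the score is a weak measure of neutrophil content. Of 32 interferon-stimulated genes 2 fell and 30 did not pass, with 7 lower adjusted over the list alone. The interferon list moved down with camera (adjusted p = 4.31e-08, and adjusted p = 0.259 with an estimated correlation). The 2 falls became 1 without room air replicates 2, 3 or 4 or smoke replicate 1. Ifi204, a sensor of DNA whose reads can be shared with related Ifi genes, fell from 395 ± 17.8 to 253 ± 19.6, while the regulator Irf7 was at 34.4 ± 3.71 against 66.7 ± 26.2 and was not called. Of 12 T cell markers 2 fell and 10 did not pass, with 7 lower adjusted over the list alone. The T cell list moved down with camera (adjusted p = 6.24e-06, and adjusted p = 0.284 with an estimated correlation). The 2 falls became 0 with limma without room air replicates 2 or 4 or smoke replicates 1 or 4, 1 without room air replicate 3 or smoke replicate 2, and 5 without room air replicate 1. Cd3e, a chain of the T cell receptor complex, was at 3.29 ± 1.36 against 16.9 ± 9.36 and was called in 1 of the 8 fits without 1 library, that without room air replicate 1 (adjusted p up to 0.154). The T cell score was highest in room air replicates 2 and 3 (5.86 and 5.61, against 3.14 to 4.72 in the other libraries), the libraries that also had the highest erythroid scores (10.58 each).

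Of 28 epithelial markers 2 fell and 26 did not pass, with the same count adjusted over the list alone. The epithelial list moved down with camera (adjusted p = 0.0195, and adjusted p = 0.765 with an estimated correlation). The 2 falls became 1 without room air replicates 2, 3 or 4 or smoke replicates 1, 2 or 4. Epcam, an epithelial adhesion molecule that some macrophages and dendritic cells also express, fell from 1538 ± 240 to 616 ± 221 normalized counts (adjusted p = 0.0139), whereas surfactant protein Sftpc was at 117 ± 25.4 against 172 ± 60.1 and was not called. The epithelial score was highest in room air replicate 3 (7.22) and smoke replicate 3 (7.20). Of 5 endothelial and fibroblast markers 1 rose, Vwf, with the same count adjusted over the list alone (camera adjusted p = 0.584 in the direction up, against a median of -0.65). Vwf went from 1879 ± 126 to 3525 ± 202 (log2 0.91, adjusted p = 0.000383), while the endothelial marker Pecam1 was at 12 ± 7.91 against 20.1 ± 11.3. Of 6 erythroid markers 0 were called with limma, edgeR, DESeq2 or voom, 0 had an unadjusted p under 0.05 and 0 passed adjusted over the list alone (camera adjusted p = 0.0561). Of the 43 lists, the 4 with under 5 measured members had no set test. Of 3 measured genes of the eosinophil list 1 rose (Ear6) and 1 fell, with the same counts adjusted over the list alone. The gene that fell was Adgre1 (2252 ± 219 against 3073 ± 208), which macrophages also express. Epx, Prg2, Ccr3 and Il5ra of that list were not among the measured, so its counts say little of eosinophils. Of 2 markers of natural killer cells, 3 of B cells and 1 of mast cells 0 were called with limma, edgeR or voom, and 0, 1 and 1 with DESeq2, with 1 of each at an unadjusted p under 0.05. Adjusted over the list alone, 1, 0 and 1 were lower.

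Of 39 lists tested, 22 passed with camera, 10 up and 12 down. Divisions of the libraries into 4 and 4 that mixed smoke with room air passed 5 to 24 lists too. A pass at the preset correlation thus cannot exclude chance. With camera 0 passed with an estimated correlation, where 7 had an unadjusted p under 0.05, and 11 passed with fry. None of the 17 marker and RNA quality scores passed an exact permutation test after adjustment (0 of 17, with 4 at an unadjusted p of 0.0286, the smallest that 70 assignments of 4 against 4 can give). Those 4 were the monocyte score (7.62 ± 0.23 after smoke against 8.36 ± 0.19), the dendritic cell score (5.74 ± 0.24 against 6.78 ± 0.41), the immediate early score (8.23 ± 0.09 against 9.09 ± 0.19) and the mast cell score, which rests on 1 gene (3.99 ± 0.35 against 5.13 ± 0.62), each with an adjusted p of 0.121 by permutation. The alveolar macrophage score was 11.42 ± 0.15 against 11.33 ± 0.08 (exact permutation p = 0.314) and the T cell score 3.71 ± 0.47 against 5.08 ± 0.8 (exact permutation p = 0.0571). The scores rest on measured markers only. Ly6c2 and Plac8 of the monocyte list and Cd3d and Trac of the T cell list were not among these.

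**Figure D4:**
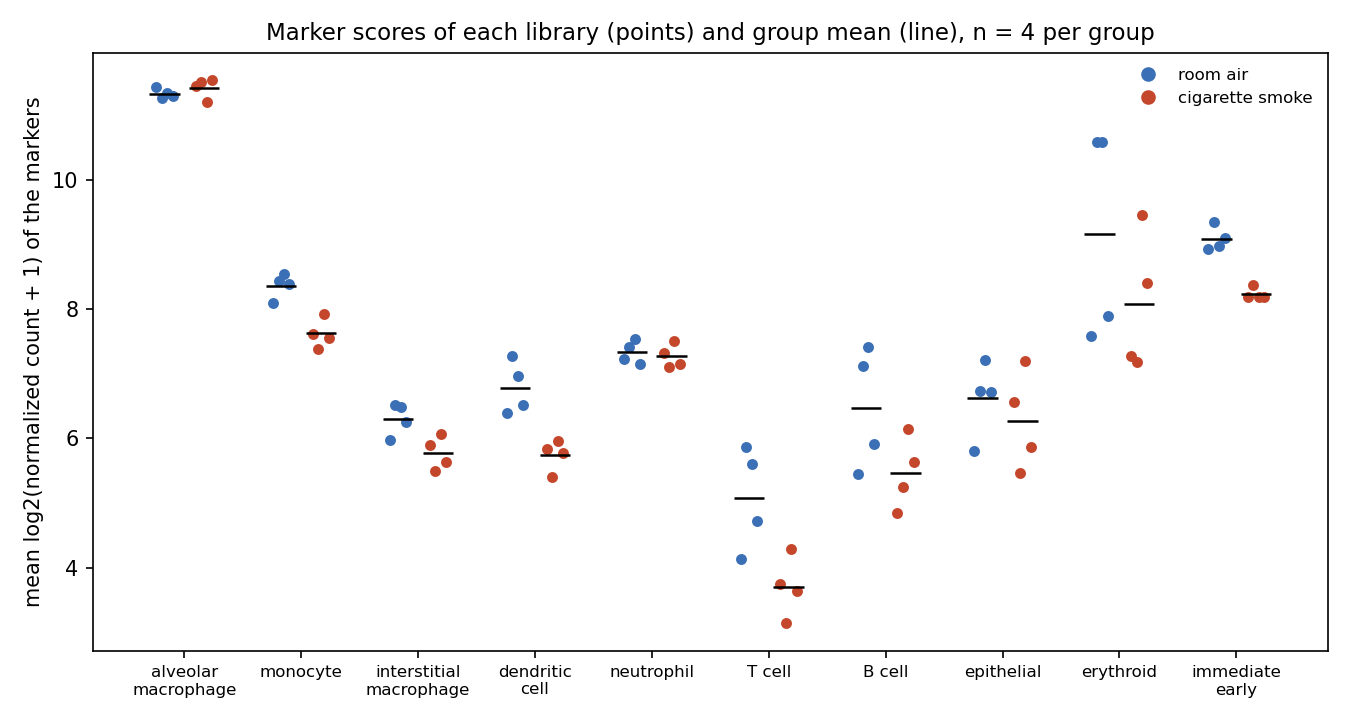
Mean log2 of (normalized count + 1) over the markers of each cell type, and over the immediate early genes, in each room air (blue) and cigarette smoke (red) library, with a line at the group mean. The groups do not overlap for the monocyte, dendritic cell and immediate early scores, and the erythroid score runs from 7.18 to 10.58.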

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

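The tests on room air replicate 1 and on the first principal component were chosen after the result was seen. In 276 sets of 4 libraries of a group, 10 had a highest or lowest library that stood far from the nearest other, measured as its gap over the range of the group. Chance gives about 5% of sets, so these 10 are no more than chance would give. Room air replicate 3 held 4 of them. Bhlhe41, which rose after smoke, was at 3526 normalized counts in it against 2503 to 2633 in the other room air libraries. The same library had 1710 counts of Apoe against 907.6 to 1033, and 744.2 of Tfrc against 285.4 to 360.8. It was low for C5ar1, at 1332 against 1601 to 1623. In smoke replicate 3, Tsku was at 143.8 against 74.6 to 82.6 in the other smoke libraries, and Plpp3 at 707 against 331 to 385. Smoke replicate 2 had 34.64 counts of Cxcl14 against 23.2 to 24.7, and an immediate early score of 8.372 against 8.186 to 8.193. Smoke replicate 4 had 526.3 counts of Zmat3 against 446 to 456. Room air replicate 4 was low for Wfdc21, at 346.3 against 393 to 400.

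On the first principal component of the log2 values (38.4% of variance), room air replicate 1 lay at -29.6, near smoke replicates 2 (-49.2) and 4 (-25.9), while the other room air libraries lay at 24.8 to 30.6. The second component (20.8%) parted the groups, with room air at 4.8 to 27.3 and smoke at -39.5 to -2.4. A mislabelled smoke library would sit with the smoke group on the genes called without it, but on a scale from 0 (room air mean) to 1 (smoke mean) replicate 1 lay at 0.33, beside room air replicate 3 at 0.32 and below the smoke libraries' own 0.79 to 0.96, which argues against it. RNA of other cell types may set the first component, and this stays open. The component rose with the mean of the T cell, B cell, epithelial and erythroid scores over the 8 libraries (Pearson r = 0.81, permutation p = 0.017). Spearman rho was 0.81 (permutation p = 0.021), and no other relation of this kind was computed. These markers are among the genes that make the component, so part of the correlation is built in and it cannot decide. Pearson r was 0.81 without the 2 libraries farthest from the median, and 0.75 within room air and 0.8 within smoke, with 4 libraries each, too few to test.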

How the results depend on the processing

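The sex term, the clock score term and the fits without the 3 libraries with the highest erythroid score were chosen after the data were seen. The 471 higher and 327 lower genes became 728 and 517 with DESeq2, and quantile normalization gave 587 higher and 551 lower genes; the cause was not tested. The clock score parts the groups, and with it as a term both counts were 0. Over the called genes the median size of the log2 change was 0.53 with the term against 0.57 without it, and the median SE 0.19 against 0.11. Without 1 library the counts ran from 210 to 418 higher and 148 to 310 lower, and without the 3 libraries with the highest erythroid score they were 210 and 159 (182 and 132 of them shared with all libraries), with fewer samples in each. Under the other alternatives the counts stayed within 1.5 times. A term for sex gave 451 and 295, edgeR 476 and 326, voom 433 and 270, TMM 571 and 420.

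The 22 lists became 0 with an estimated correlation, which allows for genes moving together, 11 with fry (10 shared) and 14 with a mean of at least 50, where fewer genes were tested; without 1 library they ran from 18 to 24. Without the 3 libraries with the highest erythroid score, cholesterol synthesis (adjusted p = 0.008645) and ribosomal proteins (adjusted p = 0.6225) took the opposite direction, while iron handling (adjusted p = 0.02189) and metallothioneins (adjusted p = 0.04614) passed and chemokines (adjusted p = 0.1062) and oxidative phosphorylation (adjusted p = 0.3303) no longer did; the cause was not tested. Of 107 named called genes 105 were called with edgeR, 107 with DESeq2, 92 with voom, 95 with the sex term, 68 without those 3 libraries and 0 with the clock score term. With the clock score term Nr1d1 (-0.072) and Tef (-0.163), which are part of the score, changed sign. The sex term ended the calls of Il12b, Cd3e, Ccne2, Pcna, Uqcrb, Nr1d1, Tef, Tgfbr2, Pfkp, Pgam1, Aldoc and Dmbt1, and voom those of genes including the first 10, Fscn1 and Rragd; edgeR ended those of Tef and Pfkp. For the marker scores the smallest exact p, 0.0286 in 4 of 17, adjusts to 0.121, so that 0 past the threshold under each alternative says nothing of their stability.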

Other observations

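The gene sets and single genes of the first paragraph, the clock genes, the marker score, clock score and Ciita tests on MHC class II, and both tests on the clock genes were chosen after the result was seen; the splits of the libraries and the test on GC content and length were planned. Of 20 measured subunits and accessory proteins of the V-ATPase, the pump that acidifies lysosomes, 9 rose with limma and the others did not pass, with a median log2 change of 0.26. Of 6 genes of the Rag GTPases and the folliculin complex, which couple lysosomes to nutrient signalling, 4 rose and the others did not pass. Fnip2 rose by 0.70, Fnip1 by 0.49 and Rragc by 0.45 on the log2 scale, while Tfeb, a regulator of lysosomal genes, was at -0.03 and not called. Of 17 glutathione transferases 3 rose, and of 4 Gimap genes, GTPases of lymphocytes, 2 fell. As these sets were chosen for what their members showed, their counts describe the values and test nothing. Cd200, the ligand of the CD200 receptor, rose by 1.23, Hpgds, a prostaglandin D synthase, by 1.49 and the growth factor Igf1 by 1.45.

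Of 10 genes of the circadian clock 4 were called with limma. Nr1d2, a repressor of the clock, rose from 335 ± 115 to 784 ± 176 normalized counts (n = 4 per group, limma adjusted p = 0.0152), and Per3 from 111 ± 27.2 to 270 ± 102 (adjusted p = 0.0195). Nr1d1 (log2 1.62, adjusted p = 0.0445) and Tef (1.45, adjusted p = 0.0492) were each kept in 2 of the 8 fits without 1 library, those without room air replicate 3 or smoke replicate 3, and Per3 was lost without room air replicates 2 or 4. Nr1d1 lies opposite Thra, and reads of the strands are not separable here. Dbp (log2 1.62), Arntl (-0.50), Nfil3 (-0.87), Npas2 (-0.90), Cry1 (-0.29) and Clock (0.16) were not called with limma, and of these edgeR and DESeq2 called Nfil3 (adjusted p = 0.0483 with edgeR).

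The groups also stand apart from other ways of dividing the libraries. Of the 35 splits of the 8 libraries into 4 and 4, only 1, the real one, gave as many as 471 genes in a direction. The same split was the only 1 with as many as 327. The highest other split, which parted male from female libraries, gave 10. As 1 of 35 is the smallest share these splits can give, this argues against chance for both counts but cannot exclude it. Every other split also mixes smoke with room air libraries, which can lower its counts. Only some of the 35 hold 2 female libraries on each side, as the real one does. For the 22 lists past the threshold, 4 of the 35 splits gave as many, with 24 in the highest other, so chance cannot be excluded. The lowest split passed 5 lists, although apart from the split by sex the others called 0 genes. A pass with camera at its preset correlation therefore cannot by itself set a list apart from chance.

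The fall of MHC class II genes may have more than 1 source. Fewer dendritic cells, monocytes and interstitial macrophages would take the fall with them, and this stays open. With the mean of their 3 marker scores as a term, the difference over the 8 called genes did not shrink. It was -2.07 (95% interval -3.02 to -1.13), against -1.6 without the term. The monocyte and dendritic cell scores themselves part the groups, so the term rests on the spread within groups and cannot decide. In room air the 3-score mean ranged over 0.59 and the class II genes over 0.11, and in smoke over 0.56 and 0.86. Taking out a trend with GC content and transcript length left a median of -1.8 against -1.91, which argues against such a bias. Lower Ciita in the cells of smoke-exposed mice stays open. Ciita changed by -1.98 on the log2 scale (SE 0.209, limma adjusted p = 0.00133, n = 4), but it is itself 1 of the 8 genes, so its fall restates the pattern and decides nothing. A different hour of lavage stays open too. With the clock score as the term the difference did not shrink (-1.73), but its 95% interval, -2.71 to -0.75, takes in -0.8, the bound that the interval with the marker scores lay beyond. Gene by gene, the median of the 8 was -1.97 (median SE 0.36) with the clock score and -1.91 (0.2) without it, and their calls ended as the errors widened.

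The rise of clock-controlled genes may come from lavage at different times of day or from smoke shifting the clock of the cells. Of the 10 clock genes, 9 lay in the direction that their known phase gives to a single shift, 5 of them among the 6 not called with limma. The clock score differed by 1.92 on the log2 scale, from -2.16 to -0.38 in room air and from -0.16 to 1.23 after smoke. The score holds the 4 called genes that led to it, so its difference restates their rise. Both explanations predict this, and they cannot be told apart, since the labels give no hour of lavage. The score parts the groups, and its use as a term left 0 genes called with limma (1483 at an unadjusted p under 0.05). Over the 798 genes called without it, the median size was 0.53 with it against 0.57 on the log2 scale and the median SE 0.19 against 0.11, and 796 kept their sign. The other 2, Nr1d1 and Tef, changed sign. No call can be assigned to smoke or to the hour by this term.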
